A study of Mus musculus with 8 samples.

How the data were processed

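The series measured polyadenylated RNA by sequencing in astrocytes isolated from newborn C57BL/6 mice. There were 4 libraries of untreated cells and 4 libraries of cells given a cocktail of interleukin-1α, tumor necrosis factor α and the complement protein C1q. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a stranded mRNA kit. Groups and replicate numbers were taken from the sample titles. The treatment labels of 3 of the cocktail libraries spell C1q with other digits, and these libraries were grouped by their titles. The labels call the 4 libraries of a group separate duplications and do not say whether they came from separate cultures or animals. The p-values therefore measure the spread between these libraries, which may be technical.

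The authors deposited FPKM values (fragments per kilobase of gene, scaled to library depth) for 21878 genes, of which 4620 were at 0 in every library. The submitters' processing notes name DESeq and the genome build mm10. The aligner and the counting program are not given in the sources used here. Gene symbols are those of the deposited table. Positions came from NCBI's annotation of GRCm38, the assembly that mm10 names, in which 21727 of the 21878 genes were found by their NCBI gene number.

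Within a gene the FPKM of different libraries stood in ratios of whole numbers, to a relative tolerance of 1e-11. This gave the whole number of fragments for all 16557 genes above 0 in at least 2 libraries, and the total behind each library. The 701 genes above 0 in 1 library only were not recovered. On 16230 simulated genes 100% of the recovered whole-number ratios were right, up to a common factor of a gene. The common factors, gene lengths and library totals were not tested in the simulation. Totals were 19399764, 19195898, 20082800 and 20640490 fragments in untreated libraries 1 to 4, and 20091686, 19322585, 20506911 and 20292407 in cocktail libraries 1 to 4. The recovered genes held between 99.86% and 99.89% of each total. A count of 0 allows up to 3 fragments, which is 0.0727 to 0.0781 FPKM for a gene of 2 kb, for counting error only.

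Replicates were compared before averaging, by a chi-square of the recovered fragments per gene for each pair of libraries, over genes with at least 20 fragments in the pair. It was 2.11 to 4.50 per gene in untreated pairs. In cocktail libraries it was 2.29 between 1 and 2, 2.55 between 3 and 4, and 4.12 to 6.79 between these pairs. All values lie above the value of 1 that sampling noise alone gives, which does not show that the libraries are separate samples. Each library entered the tests as 1 sample, following the labels.

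The main test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with a mean-variance trend and no covariate. Genes with at least 1 FPKM in at least 4 of the 8 libraries entered, 11845 in all. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes of the test are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The design fixed before the data were examined named count tools as an alternative for recovered reads. These tools were not run, although whole fragments were recovered. limma voom was fitted to the recovered fragments in their place, a choice made after seeing the data.

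Gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists with at least 3 tested members. Alternatives were camera with an estimated correlation, and fry. The lists were pan-reactive, A1 and A2 astrocyte markers, complement, NF-kB feedback, cytokines, interferon response, MHC class I, MHC class II, receptors of the cocktail, astrocyte identity, synaptogenic factors, phagocytosis, cholesterol synthesis, fatty acid synthesis, cell cycle, extracellular matrix, metalloproteases, eicosanoid and nitric oxide synthesis, oxidative stress, endoplasmic reticulum stress, cell death, glycolysis, respiratory chain, reference genes, immediate early genes, mitochondrially encoded transcripts, and markers of microglia, neurons, oligodendrocyte lineage, endothelium, mural cells, fibroblasts and ependyma. The mean log2(FPKM + 1) of each cell type list per library was compared by an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286.

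Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM. It also took up to 4 members of each list and 9 genes of prior interest, namely C3, Gfap, Vim, Lcn2, Serpina3n, Il1r1, Tnfrsf1a, Megf10 and Elovl1. The list genes Cxcl11, Mx1, Mx2, Ugt1a and the mitochondrially encoded transcripts were not analysed here.

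Fragments were simulated with the totals of these libraries. Every gene got the same extra spread, 2.2% as a coefficient of variation, the median of abundant genes in untreated libraries. Among 11750 tested genes, limma called 88% of those changed 1.2-fold, 98% at 1.5-fold and 100% at 2-fold and 4-fold, with 9 false calls among 202. Real cocktail pairs reached a chi-square of 6.79 per gene, against 4.50 in untreated pairs, and far more genes were called. These rates therefore need not hold for the real data. A simulated list raised 1.5-fold was called and none of the other simulated lists was. Genes were simulated without correlation between them, so this does not test the calls of lists whose genes vary together. Alternatives changed the pseudocount, the filter, the scaling, the library weights, the variance model, the replicate block and the libraries included. Gene Ontology terms in the deposited annotation were tested for enrichment among genes changed at least 2-fold against all tested genes with a term, for terms of 10 to 500 genes, an analysis added after the data were seen. In a self-test, 0 of 100 random gene sets gave an enriched term, and 64 of 100 planted terms were found when 25% of their members were put into the set. Genes were drawn into these sets independently, so this does not test terms whose genes vary together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.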

Results

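RNA was sequenced from mouse astrocytes, the main support cells of the brain, in 4 untreated libraries and 4 libraries treated with interleukin-1α, tumor necrosis factor α and C1q. The cocktail was used to obtain reactive astrocytes that carry C3d, a fragment of the complement protein C3. The comparison asks which genes differ between untreated and cocktail-treated cells. Depth lay between 19195898 and 20640490 fragments per library. The 10 most abundant genes of a library held 5.54% ± 0.08 (SD, n = 4) of the fragments in untreated and 7.18% ± 0.07 (SD, n = 4) in cocktail libraries.

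All 18 tested cytokine and chemokine genes rose (camera, adjusted p = 2.0e-13, and adjusted p = 0.011 with an estimated correlation), and all 22 cell cycle genes fell (camera, adjusted p = 4.1e-08, and adjusted p = 0.33 with an estimated correlation). C3, the central component of complement, rose from 1129 ± 59.3 to 3491 ± 86.4 FPKM (SD, n = 4 in each group). Saa3, an acute-phase serum amyloid gene, rose 104-fold from 13.8 ± 2.60 to 1429 ± 197 FPKM (SD, n = 4), the largest log2 change among the named genes. Lcn2, which encodes an iron-siderophore binding protein of inflamed tissue, rose from 1852 ± 61.3 to 14623 ± 430 FPKM (SD, n = 4) and held 1.25% of all fragments in treated cells. Gfap and Vim, the intermediate filament genes of astrocytes, fell from 412 ± 29.6 to 189 ± 5.41 FPKM and from 3230 ± 44.0 to 1344 ± 56.0 FPKM (SD, n = 4).

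In limma, the log2 change of C3 was 1.63 with a standard error of 0.041 and an adjusted p of 1.4e-11. For Saa3 it was 6.60 with a standard error of 0.119 (limma, adjusted p = 9.4e-13). For Gfap it was -1.12 with a standard error of 0.047 (limma, adjusted p = 9.4e-10), and for Vim -1.27 with a standard error of 0.035 (limma, adjusted p = 3.2e-11). C3 lies on chromosome 17 from 57203967 to 57228136, Saa3 on chromosome 7 from 46711998 to 46719615, Lcn2 on chromosome 2 from 32384637 to 32387739 and Gfap on chromosome 11 from 102887336 to 102897200 of GRCm38. Values are sums over each gene, so exons and transcripts were not separated.

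**Figure D1:**
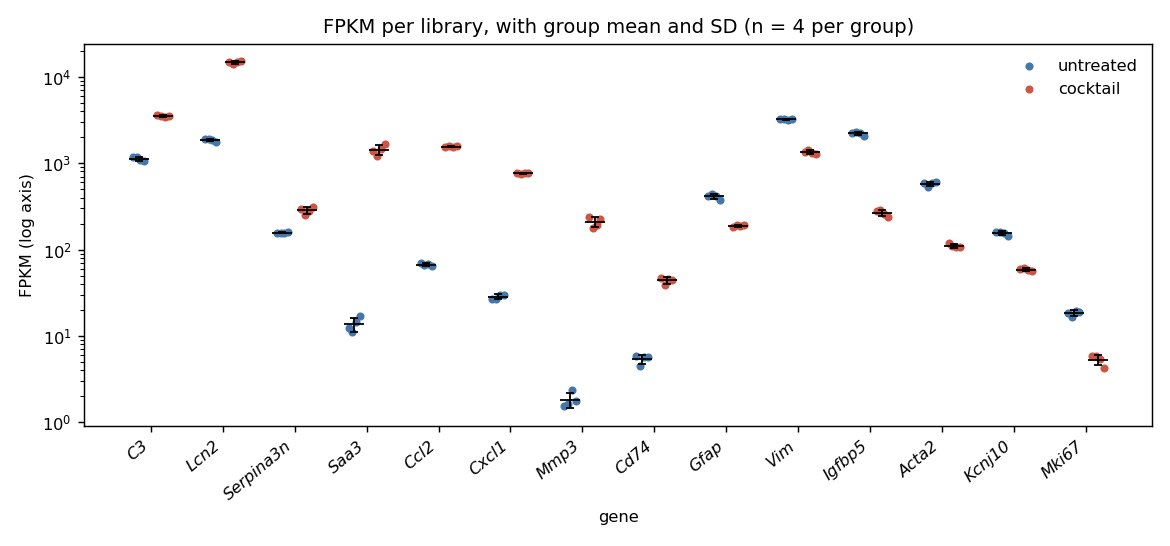
FPKM on a log axis for 14 genes in each library, untreated in blue and cocktail in red, with points for single libraries and black bars for the mean and SD of 4 libraries. C3 stands at a mean of 1129 FPKM in untreated and 3491 in cocktail libraries, while Gfap stands at 412 and 189.

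Mmp3, a matrix-degrading protease, rose 114-fold from 1.83 ± 0.374 to 209 ± 26.5 FPKM (SD, n = 4). The chemokine genes Ccl7, Ccl5, Cxcl1, Cxcl5 and Ccl2 rose 60.1-, 47.0-, 26.8-, 29.2- and 23.2-fold in mean FPKM. Cfb, complement factor B, rose from 0.917 ± 0.085 to 50.3 ± 3.88 FPKM (SD, n = 4). Gbp6, an interferon-inducible GTPase with close paralogs whose fragments the counting could have shared, rose 17.4-fold. Cdhr1, a photoreceptor cadherin, rose 34.7-fold from 0.704 FPKM.

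The largest falls included Npvf, a neuropeptide precursor gene, from 191 ± 20.4 to 14.8 ± 2.75 FPKM (SD, n = 4). Igfbp5, a binding protein of insulin-like growth factors, fell from 2203 ± 82.3 to 266 ± 23.9 FPKM (SD, n = 4). It lies on chromosome 1 from 72858065 to 72874865. Slc39a12, a zinc transporter, fell from 64.9 to 5.39 FPKM, and Ogn, a matrix proteoglycan, from 137 to 18.6 FPKM. Lect1, Fbln5, Glycam1, Dner, Sertm1 and Nnat were 17.2-, 9.45-, 11.6-, 7.33-, 8.82- and 7.43-fold lower in mean FPKM than in untreated cells.

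Of 11845 genes tested, 8023 were called, 3151 higher and 4872 lower, so that 39.3% of the calls were rises. When libraries were rescaled by median ratios, 51.8% of the calls were rises, with 4281 for genes changed by cocktail: higher, and 3976 for genes changed by cocktail: lower. The split into rises and falls therefore depends on the scaling. At least a 2-fold change was called for 483 genes higher and 540 lower. Cocktail libraries 1 and 2 also lay apart from 3 and 4 over all tested genes, at -6.30, -7.57, 4.43 and 8.61 on the principal component with 2.11% of the variance, against 93.5% for the component that parts the groups. In 7421 genes, 62.7% of those tested, the libraries of the groups did not overlap, against 2.86% expected by chance. On the recovered fragments voom gave 625 for genes changed at least 2-fold by cocktail: higher, and 930 for genes changed at least 2-fold by cocktail: lower.

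Of the 18 cytokine and chemokine genes 14 rose at least 2-fold. Of 17 tested NF-kB genes, 16 rose (camera, adjusted p = 2.0e-13, and adjusted p = 0.011 with an estimated correlation). Tnfaip2 rose from 13.5 ± 0.197 to 186 ± 11.7 FPKM, the mitochondrial superoxide dismutase gene Sod2 from 25.7 to 318, and Tnfaip3, an inhibitor of the pathway, from 7.08 ± 0.434 to 71.5 ± 2.17 (SD, n = 4). Traf1, an adaptor of tumor necrosis factor receptors, fell from 9.67 to 5.02 FPKM. Counts of called members adjusted over the list alone equalled those over all genes in every list except those named in the following text.

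Of 22 interferon response genes, 20 rose and 2 fell (camera, adjusted p = 8.1e-08). The call did not hold when the correlation was estimated (adjusted p = 0.33 with an estimated correlation). Gbp5 rose from 19.7 ± 0.342 to 220 ± 10.2 FPKM, Ifi44 from 7.12 ± 2.79 to 37.3 ± 4.93 and Oas1a from 1.64 ± 0.749 to 8.54 ± 1.86, while Ifit2 fell from 21.4 ± 0.804 to 12.6 ± 1.04 (SD, n = 4). All 15 MHC class I genes rose (camera, adjusted p = 5.1e-11, and adjusted p = 0.079 with an estimated correlation), among them Psmb8 from 25.6 to 103 FPKM, Psmb10 from 14.5 to 53.0, H2-T23 from 21.1 to 79.3 and H2-K1 from 190 to 550.0. Of 6 MHC class II genes 5 rose (camera, adjusted p = 0.0097, and adjusted p = 0.10 with an estimated correlation). Cd74, the class II chaperone, rose from 5.44 ± 0.644 to 43.9 ± 3.71 FPKM and H2-Aa from 1.00 ± 0.386 to 5.95 ± 0.429 (SD, n = 4). H2-Ab1 rose from 2.08 to 7.13 FPKM and H2-Eb1 from 0.729 to 1.63. Microglia, which can also express class II genes, had marker means of 1.14 and 1.25 in cocktail libraries 1 and 2 and of 1.82 and 2.15 in libraries 3 and 4. Fragments of H2, Gbp, Oas, C1r and C1s genes could be shared with near-identical copies, so their values are uncertain.

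Of 9 complement genes 6 rose and 2 fell, and 7 rose when adjusted over the list alone (camera, adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation). C1s1 rose from 57.5 to 267 FPKM and C1ra from 58.3 to 208, while the complement inhibitor gene Cd59a fell from 10.3 to 4.50. Of 7 receptors and binding partners of the cocktail 6 rose (camera, adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation). Tnfrsf1b rose from 2.68 ± 0.209 to 10.6 ± 2.20 FPKM, Il1r1 from 3.58 ± 0.297 to 8.24 ± 1.03 and Il1rap from 5.71 ± 0.225 to 12.4 ± 0.302 (SD, n = 4). Megf10, a phagocytic receptor that binds C1q, fell from 13.7 to 9.07 FPKM. Tnfrsf1a stood at 86.5 ± 2.13 and 91.8 ± 2.37 FPKM (SD, n = 4; limma, adjusted p = 0.021), a call that was lost without cocktail library 1 (adjusted p = 0.057), cocktail library 2 (0.056), untreated library 3 (0.060), untreated library 4 (0.054) or cocktail libraries 1 and 2 (0.17).

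Of 13 pan-reactive astrocyte markers 10 rose and 3 fell (camera, adjusted p = 0.00019, and adjusted p = 0.095 with an estimated correlation). Timp1 rose from 26.7 to 211 FPKM, Cd44 from 34.6 to 218 and Serpina3n from 156 to 283, with Vim and Gfap among the falls. Of 11 A1 markers, published for neuroinflammation, 7 rose and 3 fell (camera, adjusted p = 0.014). The A1 call was lost with an estimated correlation (adjusted p = 0.10 with an estimated correlation), after median-ratio rescaling (adjusted p = 0.051) and without genes of other lists (adjusted p = 0.60). Gbp2 rose from 55.9 to 395 FPKM and Iigp1 from 5.46 to 33.1, while Fbln5 fell from 38.5 to 4.08. Of 10 A2 markers, published for ischaemia, 5 rose and 5 fell (camera, adjusted p = 0.70). Ptx3 rose from 100.3 to 1320 FPKM, Ptgs2 from 3.22 to 20.6 and Cd14 from 11.4 to 55.2, while Emp1 fell from 30.2 to 4.51.

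Of 19 astrocyte identity genes 13 fell and 5 rose (camera, adjusted p = 0.087). The list was called downward after median-ratio rescaling (adjusted p = 0.039) and quantile normalization (adjusted p = 0.0034), both with the preset correlation, and as deposited it had an adjusted p = 0.60 with an estimated correlation. The transporter gene Slc4a4 fell from 50.7 ± 1.54 to 14.6 ± 0.567 FPKM, Aldoc from 76.7 ± 2.95 to 25.3 ± 3.78 and the potassium channel gene Kcnj10 from 155 ± 8.19 to 58.8 ± 2.04, while the glutamate transporter gene Slc1a2 rose from 9.73 ± 0.579 to 52.3 ± 1.17 (SD, n = 4). Among 13 synaptogenic factors 8 fell and 3 rose (camera, adjusted p = 0.22, 0.044 with a mean FPKM of at least 5, and adjusted p = 0.33 with an estimated correlation), with falls of Gpc4 from 175 to 78.2 FPKM, Thbs1 from 487 to 227 and Sparcl1 from 78.9 to 47.6, and a rise of Thbs2 from 21.3 to 50.1. Among 14 phagocytosis genes 8 fell and 4 rose (camera, adjusted p = 0.42), with Gulp1 falling from 21.2 to 8.80 FPKM, Itgb5 from 87.7 to 43.6 and Mertk from 1.51 to 0.386, and Axl rising from 61.1 to 88.2.

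Of the 22 cell cycle genes 21 fell at least 2-fold. Mki67, a marker of proliferating cells, fell from 18.5 ± 1.30 to 5.34 ± 0.721 FPKM, Ccna2 from 19.4 ± 1.69 to 5.28 ± 1.17, Aurkb from 12.7 ± 1.10 to 3.13 ± 0.259 and Rrm2 from 48.9 ± 4.31 to 13.9 ± 2.64 (SD, n = 4). Of 23 cholesterol synthesis genes 17 rose and 1 fell, and 18 rose when adjusted over the list alone (camera, adjusted p = 2.1e-05, and adjusted p = 0.045 with an estimated correlation). Acat2 rose from 11.8 to 21.4 FPKM, Fdps from 21.5 to 35.8 and Mvd from 6.83 to 11.7, while Sqle fell from 56.2 to 48.8. No member changed 2-fold. Of 13 fatty acid genes 7 fell and 4 rose (camera, adjusted p = 0.70). The desaturase genes Fads2 and Fads1 fell from 444 to 278 and from 120 to 82.8 FPKM, Elovl5 fell from 65.0 to 42.7, Elovl7 rose from 1.29 to 3.36 and Elovl1 rose from 14.2 ± 0.387 to 16.7 ± 0.575 (SD, n = 4).

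**Figure D2:**
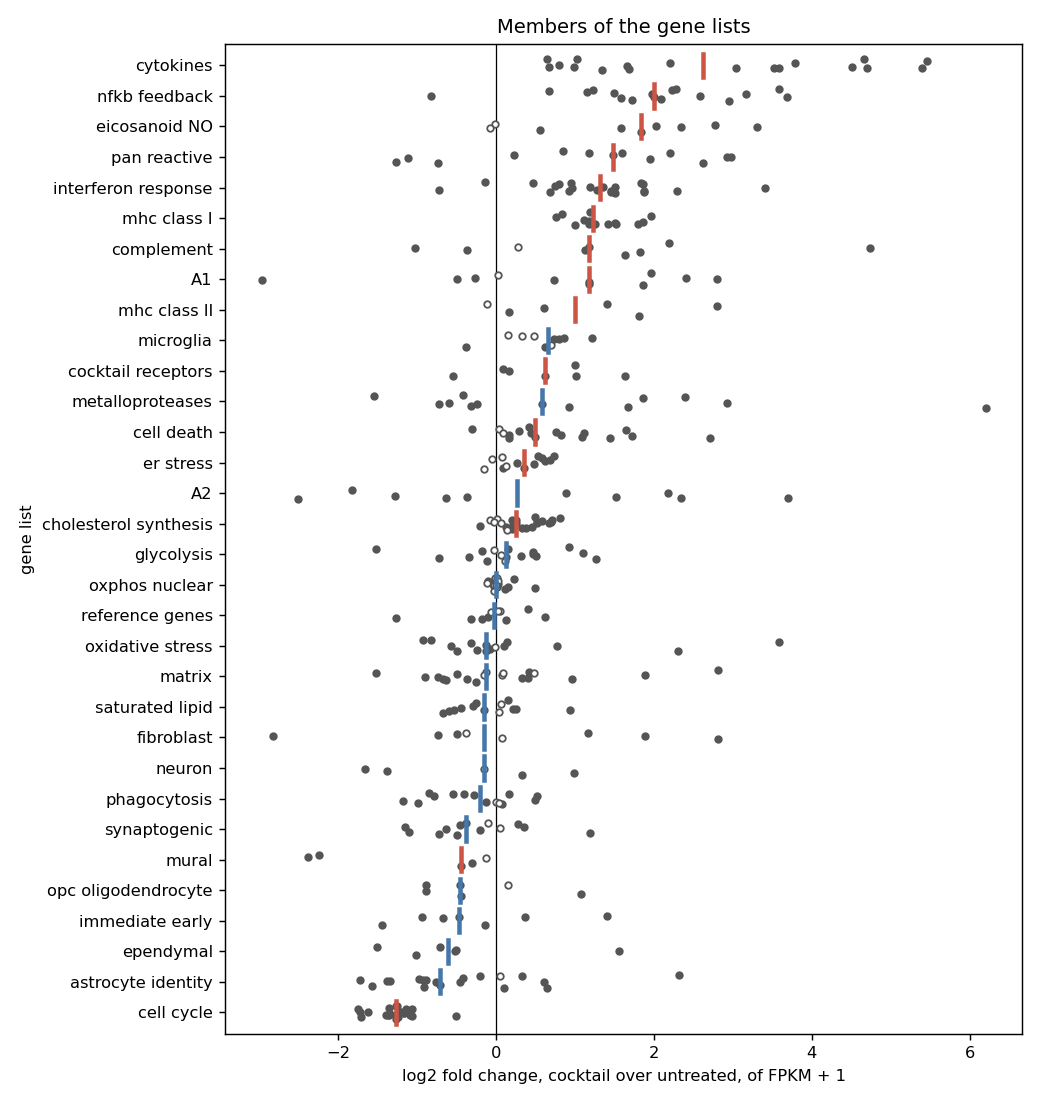
Log2 fold change of FPKM + 1, cocktail over untreated, for every tested member of the gene lists; filled points are called genes, open points are not. Bars mark list medians, red where camera with a preset correlation called the list and blue otherwise, from a median of -1.27 for cell cycle genes to 2.62 for cytokines.

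Of 9 genes of prostaglandin and nitric oxide synthesis 7 rose (camera, adjusted p = 3.4e-05, and adjusted p = 0.11 with an estimated correlation), including the inducible nitric oxide synthase gene Nos2 from 0.25 ± 0.103 to 11.4 ± 0.807 FPKM and Ptges from 4.17 ± 0.394 to 34.3 ± 1.62 (SD, n = 4). Pla2g4a, which releases arachidonic acid, rose from 10.7 to 46.8 FPKM. Of 17 cell death genes 14 rose and 1 fell (camera, adjusted p = 3.7e-06, and adjusted p = 0.10 with an estimated correlation), with Zbp1 rising from 1.40 to 14.7 FPKM, Bid from 8.44 to 30.2 and Casp4 from 14.2 to 46.4. Of 13 endoplasmic reticulum stress genes 9 rose (camera, adjusted p = 0.0011, and adjusted p = 0.095 with an estimated correlation), with Hspa5 rising from 181 to 293 FPKM, Calr from 297 to 457, Xbp1 1.52-fold and Atf3 from 5.65 to 10.1. Among 15 oxidative stress genes 9 fell and 5 rose (camera, adjusted p = 0.84). Hmox1 fell from 155 to 81.9 FPKM, Mt1 from 253 to 143 and Gclm from 46.1 to 30.8. The median of that list was -0.12, its mean 0.21 and camera's direction downward.

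Among 17 glycolysis genes 9 rose and 5 fell, with 10 rises when adjusted over the list alone (camera, adjusted p = 0.063). The lactate transporter gene Slc16a1 rose from 79.8 to 195 FPKM, Pfkfb3 from 27.3 to 59.6 and Pfkl from 22.5 to 43.7, while Pfkp fell from 74.9 to 25.4. The glycolysis list was called without cocktail library 1 (adjusted p = 0.040), 2 (0.034), 4 (0.048) or both 1 and 2 (0.015). It was also called without the filter (camera, adjusted p = 0.032), without genes of other lists (0.035) and with voom (0.0498). All these calls use the preset correlation, and over all libraries the list had an adjusted p = 0.60 with an estimated correlation. Of 20 respiratory chain genes 4 rose and 2 fell, or 3 and 1 when adjusted over the list alone (camera, adjusted p = 0.36), with Cox6c rising from 170 to 238 FPKM and Sdhb from 54.0 to 60.1. Ndufa4 stood at 177 and 165 FPKM (limma, adjusted p = 0.046), a call lost without any 1 of untreated libraries 1, 2, 3 and 4 (adjusted p = 0.13, 0.053, 0.062 and 0.076) or cocktail libraries 1, 3 and 4 (0.13, 0.099 and 0.056). That call was also lost after median-ratio rescaling (limma, adjusted p = 0.66), without the filter (0.077), without the variance trend (0.080) and without cocktail libraries 3 and 4 (0.12). Of 19 matrix genes 8 fell and 6 rose (camera, adjusted p = 0.70), with a median of -0.13, a mean of 0.085 and an upward test direction. Lama2 fell from 7.43 to 1.94 FPKM, Col5a2 from 154 to 81.9 and Col1a2 from 53.7 to 32.1. Of 13 metalloprotease genes and inhibitors 7 rose and 6 fell (camera, adjusted p = 0.15, 0.047 without the filter, and adjusted p = 0.33 with an estimated correlation), including Mmp9 from 0.183 to 5.20 FPKM and the inhibitor gene Timp3, which fell from 433 to 148.

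Of 7 immediate early genes 5 fell and 2 rose (camera, adjusted p = 0.59), with Dusp1 falling from 32.5 to 11.3 FPKM, Fos from 7.98 to 3.70 and Egr1 from 5.04 to 2.80, and Junb rising from 39.7 to 107. Of 10 reference genes 4 fell and 3 rose (camera, adjusted p = 0.88). Actb, the cytoplasmic actin gene, fell from 997 ± 36.9 to 416 ± 19.9 FPKM (SD, n = 4), Ywhaz from 103 to 82.5 and Pgk1 from 248 to 218, while Rpl13a rose from 231 to 354. The median of the reference genes was -0.019, their mean -0.069 and camera's direction upward. The respiratory chain list had a median of -0.0057, a mean of 0.032 and an upward direction.

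Markers of other cells that such cultures can hold also differed. Of 10 tested microglial genes 5 rose and 1 fell, with 6 rises when adjusted over the list alone (camera, adjusted p = 0.15, and called without cocktail library 1 at 0.032, without the filter at 0.038 and without cocktail libraries 1 and 2 at 1.2e-04). These calls use the preset correlation, and over all libraries the list had an adjusted p = 0.75 with an estimated correlation of 0.82 between its genes. Fcer1g stood at 2.15 ± 0.240 FPKM in untreated and 7.29 ± 4.65 in cocktail libraries (SD, n = 4; limma, adjusted p = 0.0053), Cd68 at 3.83 ± 0.389 and 8.05 ± 2.78 (SD, n = 4; limma, adjusted p = 0.00079). Itgam stood at 0.910 ± 0.244 and 2.62 ± 1.81 FPKM (SD, n = 4; limma, adjusted p = 0.022), a call lost without untreated library 2 (adjusted p = 0.0504), untreated library 4 (0.057) or cocktail library 3 (0.063), without the filter (0.055) and in the robust fit (0.078). Its values in cocktail libraries 1 to 4 were 1.21, 1.18, 3.08 and 4.99 FPKM, and without libraries 3 and 4 its log2 change went from 0.80 to 0.21 (limma, adjusted p = 0.13). The mean log2(FPKM + 1) of 18 microglial genes was 1.16 ± 0.070 in untreated and 1.59 ± 0.480 in cocktail libraries (SD, n = 4; exact permutation test, p = 0.14, adjusted p = 0.14), and without cocktail library 1 the adjusted exact p was 0.033.

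Of 5 mural genes 4 fell, and 5 when adjusted over the list alone (camera, adjusted p = 0.021, and adjusted p = 0.33 with an estimated correlation), a call also lost without the filter (adjusted p = 0.056). The smooth muscle actin gene Acta2 fell from 581 ± 31.7 to 111 ± 5.48 FPKM and Tagln from 555 ± 32.0 to 116 ± 5.72 (SD, n = 4), against 20.4 to 16.4 for Pdgfrb and 1.56 to 0.879 for Rgs5. Both tested endothelial genes fell, Slco1a4 from 98.2 to 22.9 FPKM and Kdr from 3.99 to 0.616. Of 6 ependymal genes 5 fell and Rarres2 rose from 18.4 to 56.1 FPKM (camera, adjusted p = 0.18), with Foxj1 falling from 116 to 70.9, Dynlrb2 from 19.6 to 6.28 and Rsph1 from 15.5 to 7.16. Of 6 oligodendrocyte lineage genes 4 fell (camera, adjusted p = 0.32, 0.023 with a mean FPKM of at least 5, and adjusted p = 0.45 with an estimated correlation), Olig1 from 139 to 74.8 FPKM, Cnp from 47.8 to 25.4 and Olig2 from 24.9 to 17.8, while Pdgfra rose from 0.934 to 3.07. Of 5 neuronal genes 2 fell and 2 rose (camera, adjusted p = 0.75), with Stmn2 falling from 125 to 38.8 FPKM and Gad1 and Syn1 rising from 1.11 to 3.21 and from 2.42 to 3.31. Of 8 fibroblast genes 3 rose and 3 fell, or 4 fell when adjusted over the list alone (camera, adjusted p = 0.74), with Lum rising from 0.237 to 7.69 FPKM, Dcn from 1.45 to 8.31 and Aldh1a2 from 0.795 to 3.05. The median of the fibroblast list was -0.15, its mean 0.19 and its test direction upward.

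As means over each list, cocktail minus untreated, the mural markers stood at -0.57, the ependymal at -0.39, the endothelial at -0.34, the oligodendrocyte lineage at -0.11 and the neuronal at -0.086 on the log2 scale, each with an exact permutation p of 0.0286, the smallest that the design allows, and an adjusted p of 0.040. In each of these 5 lists all 4 cocktail libraries lay below all 4 untreated ones. Such means can rest on few genes and do not show that a list fell as a set. Of 10 endothelial genes only Slco1a4 and Kdr were tested, with log2 changes of -2.05 and -1.63. Acta2 and Tagln changed by -2.38 and -2.25, against -0.30 for Pdgfrb. Of the neuronal genes tested 2 fell, Stmn2 by -1.66, and 2 rose. The neuronal difference kept its size but was not called without untreated library 1 (-0.091), 2 (-0.089), 3 (-0.079) or 4 (-0.085), each with an adjusted exact p of 0.080. After median-ratio rescaling it was -0.057, with the same adjusted exact p. With a pseudocount of 0.1 neither the neuronal difference (-0.023, adjusted exact p = 0.60) nor that of the oligodendrocyte lineage (-0.074, adjusted exact p = 0.16) was called. In all these settings the mural, ependymal and endothelial lists stood at an adjusted exact p of 0.05, the threshold itself. Fibroblast markers stood at 0.15 (exact permutation test, p = 0.11, adjusted p = 0.13), at an adjusted exact p of 0.033 without cocktail library 2, and at 0.41 with a pseudocount of 0.1 (adjusted exact p = 0.05).

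**Figure D3:**
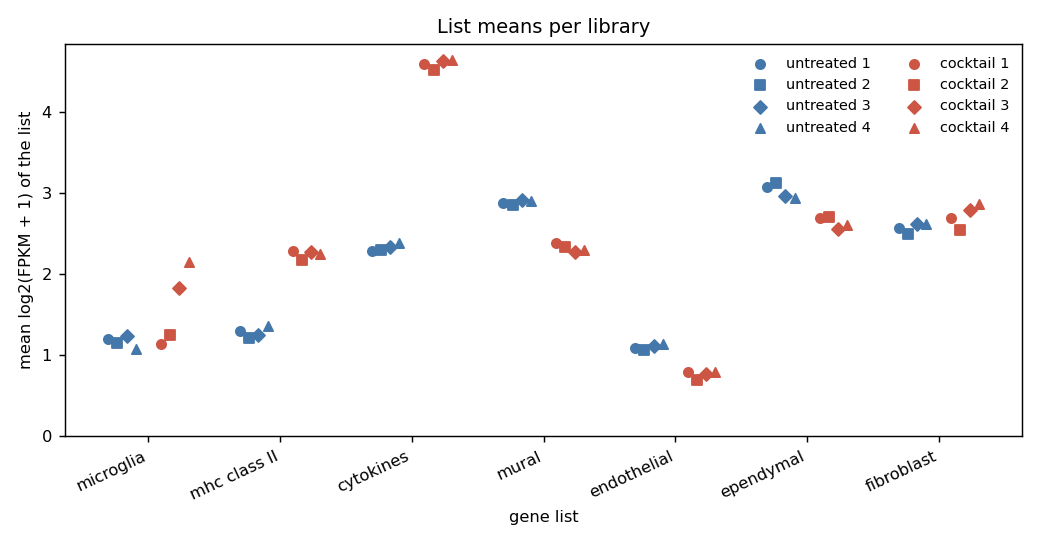
Mean log2(FPKM + 1) of 7 gene lists in each library, with colours for the groups and marker shapes for the library numbers. The microglial list stands at 1.14, 1.25, 1.82 and 2.15 in cocktail libraries 1 to 4, whereas the MHC class II list lies between 2.17 and 2.28 in all 4.

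Without cocktail libraries 3 and 4, which held the highest microglial means, 7577 genes and 15 lists were called, and the count of genes changed at least 2-fold by cocktail was 966, a setting chosen after seeing the data. The list calls are sensitive to the correlation between genes, since 15 were called with the preset and 3 with the estimated correlation.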

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

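In 350 groups of 4 values, covering named genes, list means and library totals, 13 held a library whose distance from the nearest other exceeded the critical share of the range for 4 values, which is 3.71% of the groups, and chance gives about 1 in 20. In untreated cells Cdhr1 was lowest in library 2 at 0.508 FPKM, Lcn2 in library 4 at 1761, Vim in library 3 at 3164, H2-Ab1 in library 2 at 1.66, Ccna2 in library 2 at 16.9 and Lama2 in library 1 at 6.94. Among untreated libraries Hmox1 was highest in library 3 at 160 FPKM, Pfkp in library 2 at 77.1, Aldh1a2 in library 3 at 1.10 and Dusp1 in library 4 at 35.5. The mean log2(FPKM + 1) of the cocktail receptor list was lowest in untreated library 1 at 3.06. In cocktail libraries Nos2 was lowest in library 2 at 10.2 FPKM, and the mean of the astrocyte identity list was lowest in library 3 at 5.85. No library stood out in its total of fragments.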

How the results depend on the processing

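The fit to recovered fragments, the settings without a pair of cocktail libraries and a leave-one-out with a lower filter were chosen after seeing the data. The planned count tools were not run. Counts of called genes ranged from 5822 (mean FPKM of at least 5, fewer genes tested) to 9189 (no filter), against 8023. Of these 8023 calls 7127 were kept in the same direction after median-ratio rescaling, 7204 after quantile normalization and 7868 with voom, and 2 turned under quantile normalization. The count of genes changed at least 2-fold by cocktail: lower, 540, was 893 with a pseudocount of 0.1, 930 with voom on recovered fragments and 334 with a mean FPKM of at least 5; a smaller added value shrinks low genes less, and the stricter filter tests fewer genes. All genes changed at least 2-fold by cocktail, 1023, were 1555 with voom. Leaving out 1 library gave 7298 to 7643 called genes (2823 to 3015 higher, 4351 to 4762 lower), 904 to 968 genes changed at least 2-fold (392 to 498 higher, 461 to 562 lower), 15 to 17 lists and 4 to 6 cell types. That filter asks for 4 of the 7 libraries left. At 3 libraries the ranges were 7669 to 7864 and 991 to 1061. The low end of 4 cell types was reached without 1 untreated library. There the mural, ependymal and endothelial lists stood at the threshold itself and were counted. The rule asks for an adjusted p under the threshold, so read strictly it does not call them in these settings. Without cocktail libraries 1 and 2, 7665 genes and 17 lists were called. The replicate block gave 7950 calls. Deviations of libraries with the same number correlated at -0.044, 0.078, 0.086 and -0.0071, so the numbers were not taken to pair libraries. The mean of the interferon response list was nevertheless highest in libraries 3 and 4 of both groups. The cell cycle mean was highest in untreated library 3 and in cocktail library 2. Whether the numbers mark a shared batch for some genes was not tested. Of 15 lists called, 3 were called with an estimated correlation (NF-kB, cytokines, cholesterol synthesis) and 27 with fry, which does not compare a list with other genes. Among the lists that fry called, the direction turned for oxidative stress (median -0.12), fibroblast markers (median -0.15) and reference genes (median -0.019); the cause was not tested. Of 141 named genes 138 kept direction and call in every setting that tested them (123 were tested with a mean FPKM of at least 5, and 136 or 138 with 1 library left out); Itgam, Ndufa4 and Tnfrsf1a lost the call in some. Depth limits genes near 1 FPKM.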

Other observations

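Terms and genes in this paragraph and the next were chosen after their values were seen. Among 2802 Gene Ontology terms tested per direction, 130 were enriched among genes at least 2-fold higher and 65 among genes at least 2-fold lower. The hypergeometric test takes genes as independent, so its p-values can be too small for terms whose genes vary together. Of 17 tested chemokine activity genes, 14 rose at least 2-fold (hypergeometric test, adjusted p = 5.6e-15), including Cxcl16 from 4.83 ± 0.261 to 79.6 ± 2.65 FPKM and Cxcl12 from 3.27 ± 0.392 to 48.1 ± 4.78 (SD, n = 4 libraries). Of 10 acute-phase genes 5 did (hypergeometric test, adjusted p = 0.0011), with Lbp, which binds bacterial lipopolysaccharide, rising from 89.1 to 247 FPKM and Hp from 0.225 to 5.89. Of 41 genes of defense against Gram-positive bacteria 18 did (hypergeometric test, adjusted p = 1.1e-12), with the receptor gene Tlr2 rising from 23.2 to 142 FPKM and Ripk2 from 12.1 to 66.8. Of 22 cytokine receptor genes 8 were at least 2-fold higher (hypergeometric test, adjusted p = 7.8e-05), such as Ifngr1 from 30.5 to 68.1 FPKM and Il13ra1 from 7.30 to 23.5, while Il17rb fell from 1.94 to 0.304.

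Among genes at least 2-fold lower, the term for basement membrane held 15 of 71 genes (hypergeometric test, adjusted p = 0.00014), with the netrin gene Ntn4 4.58-fold lower and Nid2 falling from 70.5 ± 1.17 to 27.2 ± 1.61 FPKM (SD, n = 4). The term for collagen trimers held 12 of 39 (hypergeometric test, adjusted p = 2.9e-05), with Col11a1 falling from 35.7 to 8.62 FPKM. Other members were at least 2-fold higher, 6 of the basement membrane term, such as Lama4 from 7.48 to 28.8 FPKM, and 3 of the collagen term, such as Col23a1 from 7.10 to 53.6. The wider term for proteinaceous extracellular matrix was enriched in both directions, with 41 of 185 genes lower (hypergeometric test, adjusted p = 3.6e-14) and 24 higher (adjusted p = 3.2e-05). Voltage-gated ion channels held 11 of 50 (hypergeometric test, adjusted p = 0.0015), with Cacna1d falling from 5.77 to 1.19 FPKM, while the potassium channel gene Kcnf1 rose from 7.56 ± 0.523 to 87.2 ± 2.74 (SD, n = 4). Binding of insulin-like growth factors held 5 of 17 (hypergeometric test, adjusted p = 0.037), with Ctgf falling from 397 to 64.1 FPKM, Cyr61 from 382 to 108 and Igfbp2 from 1932 to 683. In the same term Igfbp3 rose from 203 to 436 FPKM and Igfbp7 from 168 to 453.

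In what follows, the tests of depth, of the MHC class II genes, of mural cells, of scaling and of other splits were chosen after the results were seen, and those on another microglial list and on SRF-regulated genes were written before their values were seen. The class II test replaced an earlier one that compared single libraries. Microglial markers were highest in cocktail libraries 3 and 4. Another list of 12 microglial genes, 10 of them above a mean of 0.1 FPKM, was higher in library 4 than in library 1 by a median of 1.00 on the log2 scale, in 10 of 10 genes, with Lyz2 at 76.7, 69.3, 184 and 239 FPKM in cocktail libraries 1 to 4. The totals of libraries 4 and 1 stood in a ratio of 1.01, so their depth hardly differed. This comparison adds little, since FPKM are already scaled to depth and a difference in totals would not by itself raise them. Gpr34 and Siglech, left out by the limit of 0.1 FPKM, were at 0 in all cocktail libraries. Of the first list P2ry12 stood at 0.135 and 0.114 FPKM in libraries 1 and 4, near the floor, and Cx3cr1 at 0.133 and 1.35. More RNA of microglia or other macrophages in these libraries is a candidate explanation. The markers do not tell these cells apart, and no biological cause was tested.

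The rise of MHC class II genes did not follow the microglial markers. Over the 4 cocktail libraries the mean of the class II list ranged over 0.11 on the log2 scale and that of the microglial list over 1.02. Cd74 stood at 47.2, 38.6, 45.4 and 44.4 FPKM in cocktail libraries 1 to 4, against 4.49 to 5.90 in untreated libraries. This argues against more microglial RNA as the source of the rise. A response of the astrocytes themselves may account for it, and class II expression induced in a constant small number of other cells stays open.

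Acta2, Tagln and Actb fell together. A loss of cells carrying Pdgfrb, Rgs5 and Notch3 would lower these markers as much as Acta2 and Tagln, if no other cells expressed them. Their median log2 change was -0.30, which is the value of Pdgfrb. Whether other cells in the cultures expressed these markers was not tested. Rgs5 lay near 1 FPKM, where the added 1 shrinks changes. A loss of smooth muscle cells low in these markers was not tested. Rescaling did not remove the fall, since Actb stayed at -1.18 under the rescaling that moved it most. The median-ratio factors lay between 0.969 and 1.03, and both rescalings take most genes as unchanged. They therefore cannot exclude an error of scaling shared by most genes. Of 20 other genes regulated by the transcription factor SRF 17 fell and 2 rose, with a median of -0.65. Of all 11845 tested genes 4872 fell and 3151 rose. Among the SRF-regulated genes Myl9 fell from 286 ± 16.4 to 57.6 ± 3.99 FPKM and Cnn2 from 203 ± 7.91 to 58.7 ± 2.28 (SD, n = 4). Other changes were small, with log2 changes of -0.17 for Srf itself and -0.11 for Tpm4. The 2 rises were Lima1 at 0.29 and Filip1l at 0.36. For this list camera gave p = 1.5e-05 with the preset and p = 0.097 with an estimated correlation. Lower SRF activity may therefore underlie the fall but is not settled by these data. These genes alone cannot tell lower SRF activity from fewer cells that express them strongly.

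The 8 libraries can be split into 4 and 4 in 35 ways. For genes called, 1 of 35 splits, the real one, reached 8023, and the highest other gave 0. For genes changed at least 2-fold, 1 of 35 reached 1023, and the highest other gave 0. Every other split mixed the groups, which puts the treatment difference into the spread, so the counts of 0 add no support. The rank of the real split argues against a chance division of these libraries for both counts. It cannot exclude a chance difference between cultures, since the libraries of a group may be technical. For gene lists 4 of 35 splits reached 15, and the highest other gave 16, so chance cannot be excluded for that count by this measure. The 3 other splits each exchanged 1 library of each group and so kept part of the treatment contrast, while splits with 2 libraries of each group on either side gave at most 4 lists.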
